A study of Mus musculus with 30 samples.

How the data were processed

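RNA was sequenced from 30 preparations of pancreatic islets, the endocrine clusters of the pancreas that hold the insulin-secreting beta cells, taken from male wild-type C57BL/6N mice. Per the labels, mice were given vehicle or 1 mM cadmium chloride for 6 or 18 weeks, or islets already isolated were cultured for 96 hours with vehicle or 0.5 uM cadmium chloride. Cadmium is a toxic metal that binds thiol groups and competes with zinc, and islets are rich in zinc. The route of dosing and the ages of the mice are not given in the sources used here. Islets were purified on a Biocoll density gradient and total RNA was extracted with Trizol, per the labels' protocols. The labels give 5 vehicle and 4 cadmium libraries at 6 weeks, 6 vehicle and 5 cadmium libraries at 18 weeks, and 5 of each in culture. Nothing in them says that libraries of 1 group came from separate animals or cultures, and every p-value measures only the spread between these libraries, which may be technical.

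The values analysed are the raw read counts per Ensembl gene that the authors deposited for each library, with no normalization applied to them. Per the submitters' processing notes, cutadapt 1.13 (read trimming), STAR (alignment), HTSeq 0.6.1p1 (counting), DESeq2 and the mouse build mm10 were used upstream. The roles in brackets are what these tools usually do. The annotation release, the handling of reads that map to several places and the strand setting are not given in the sources used here. Counts of near-identical copies (the trypsinogens Try4, Try5 and Prss genes, Ins1 and Ins2, amylases, globins and ribosomal protein genes with their pseudogenes) are therefore uncertain, as are those of overlapping and antisense genes. Each library lists 54232 gene IDs, of which 54079 (99.72%) matched a symbol. The 153 unmatched IDs held at most 0.0172% of a library's counts. Where a symbol stood on several IDs (98 cases), the ID with the most counts was used. Coordinates are those of the GENCODE annotation of build mm10 (GRCm38). The 13 protein-coding genes of the mitochondrial genome had 0 counts in every library, so the list of these genes could not be tested.

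Total counts ranged from 49564350 to 58366797 at 6 weeks and from 24197072 to 26549350 in culture. At 18 weeks they ranged from 9092759 to 51852364, and 3 libraries (vehicle 4, vehicle 6 and cadmium 5) stood below the others at 14751249, 9092759 and 21573301. A chi-square comparison of the counts of genes with at least 20 reads over 61 pairs of libraries within groups gave a lowest value of 2.77 per degree of freedom and 0 identical pairs. Every library was therefore kept as its own sample.

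Each cadmium comparison was fitted on its own 2 groups with the quasi-likelihood test of edgeR 4.0.16 in R 4.3.3, after filterByExpr (minimum count 10, minimum total 15) and scaling by TMM, the trimmed mean of M values, which sets library sizes so that most genes do not differ. Benjamini-Hochberg adjusted p-values under 0.05 were called. Log2 fold changes are cadmium over vehicle, given ± SE, and levels are CPM, read counts divided by TMM-scaled library sizes and brought to a common size, given ± SD. Differences of the cadmium effect between settings were contrasts in 1 fit of all 6 groups, and vehicle at 18 weeks was compared with vehicle at 6 weeks in a fit of those 2 groups. Gene lists were tested with camera of limma 3.58.1 on log2 CPM (prior count 2) with a preset correlation of 0.01 between genes, two-sided, with Benjamini-Hochberg adjustment over the lists of a comparison that had at least 3 genes measured. No list in any of the 3 settings kept its call when the correlation was estimated per list. Other splits of the same libraries also called lists, a median of 13 at 6 weeks, 11 at 18 weeks and 9 in culture without pairs. A camera call alone is therefore weak evidence of a cadmium effect. Shares of counts were compared by exact two-sided permutation tests with Benjamini-Hochberg adjustment over the 4 shares of a comparison that were not 0.

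The groups, tests, alternatives and 42 gene lists were set before the data were examined. The lists covered metallothioneins and zinc transport, iron and copper handling, NRF2 targets and glutathione, antioxidant enzymes, heat shock, and the unfolded protein and integrated stress responses. They also covered beta cell identity, insulin secretion machinery, secretory granule biogenesis, disallowed and dedifferentiation genes, cell cycle, p53 targets, inflammation, interferon response and class I antigen presentation. Further lists held nuclear oxidative phosphorylation genes, the mitochondrial genome, glycolysis, hypoxia, cholesterol biosynthesis, fatty acid synthesis and oxidation, the circadian clock, immediate early genes, glucocorticoid targets, autophagy, proteasome, ribosomal proteins and the Reg family. Markers of alpha, delta and PP, acinar, ductal, endothelial, macrophage, lymphocyte, stellate and fibroblast, Schwann, adipocyte, erythroid and mesothelial cells were also listed. Genes were named by a rule. It took a panel of 14 (Mt1, Mt2, Slc30a1, Hmox1, Nqo1, Ins1, Ins2, Gcg, Sst, Ppy, Pdx1, Mafa, Slc2a2 and Slc30a8). To these it added the 8 rising and 8 falling genes of largest fold change past the threshold with a mean of at least 1 CPM and no predicted gene or pseudogene, the 3 of smallest p where fewer than 3 passed, and up to 4 of smallest p from each list that passed. For differences between settings and the vehicle comparison it took 5 in each direction. The text gives a part of these, 3 further genes that were tested are not reported here, and a gene outside the rule is said to be one.

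The culture groups share replicate numbers 1 to 5, and libraries of 1 number deviated together from their group means. The 5 correlations across genes ranged from 0.194 to 0.495, above the limit of 0.1 set for pairing, and each cadmium library correlated best with the vehicle library of its own number. The pairing comes from these numbers and this check, since the labels do not say what a number marks. A fit with the number as a block is therefore given beside the culture results.

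Alternatives were DESeq2 1.42.0, RLE size factors, no count filter, limma-voom with library weights, 1 surrogate variable of sva 3.50.0, the acinar share of counts as a covariate, acinar and Reg genes left out, all 30 libraries in 1 fit, a threshold of 0.1, and leaving out each library in turn. Leaving out the 3 libraries of lowest depth and variations of the blocked fit were chosen after seeing the data. Counts were also simulated with 200 genes changed, drawn from genes averaging over 1 CPM. Each gene was simulated on its own. Apart from the culture pairs in the blocked fit, structure shared between genes was not kept, so recovery in the real data may be lower. The fit recovered 74.6%, 94.0% and 100% of changes of 1.5, 2 and 4-fold at 6 weeks (18080 genes simulated) and 53.7%, 89.6% and 100% at 18 weeks (20911 genes). In culture it recovered 86.6%, 94.0% and 100% (16743 genes), and 92.5%, 100% and 100% with the block (17702 genes). Of the simulated calls, 5.29% at 6 weeks, 5.81% at 18 weeks, 5.56% in culture and 10.6% in culture with the block were false. Of differences between settings of 1.5, 2 and 4-fold, 58.2%, 73.1% and 97.0% were recovered for 18 against 6 weeks (22721 genes). For culture against 18 weeks 55.2%, 74.6% and 93.9% were. These simulations of differences gave every setting the same spread per gene. In the real libraries the biological coefficient of variation, the spread beyond counting noise, was 0.212 at 18 weeks, 0.133 at 6 weeks and 0.0686 in culture. The shares recovered for differences therefore may not carry over to the real data. For the vehicle comparison 95.5% of 2-fold changes were recovered (20551 genes).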

Results

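The series measured the islet transcriptome after 6 and 18 weeks of cadmium exposure of male mice and after 96 hours of exposure of isolated islets, so that each exposure could be set against its own vehicle group. Total counts at 6 weeks were 49564350 to 55504925 in the 5 vehicle and 49953778 to 58366797 in the 4 cadmium libraries. At 18 weeks vehicle libraries 4 and 6 held 14751249 and 9092759 counts and the other vehicle libraries 41821402 to 51404595. Cadmium library 5 of that time held 21573301 counts and the others 46814618 to 51852364. The 10 culture libraries held 24197072 to 26549350 counts. The first principal component carried 52.7% and the second 26.6% of the variance over 22721 genes.

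Transcripts of acinar cells, the exocrine cells that make digestive enzymes and surround the islets, took a larger share of counts with cadmium at 18 weeks. The 34 acinar marker genes held 0.844% ± 0.516 (SD, n = 6) of counts in vehicle and 8.08% ± 6.98 (SD, n = 5) in cadmium libraries, a ratio of means of 9.58 (exact permutation test over 462 arrangements, p = 0.00433, adjusted p = 0.0173). The cadmium libraries stood at 3.56, 1.61, 9.43, 19.4 and 6.43%, and 4 of these 5 lay above all vehicle libraries. Without vehicle library 1, 3, 4, 5 or 6 the adjusted p of the exact permutation test was 0.0635, with a difference of 7.12 to 7.25 percentage points against 7.24 with all libraries. With 5 libraries in each group every arrangement has a mirror of the same absolute difference, so the test has coarser steps there. Without cadmium library 4 the difference was 4.41 points (exact permutation test, adjusted p = 0.0381), and without cadmium library 2 it was 8.86. At 6 weeks the share was 3.70% ± 0.837 (SD, n = 5) in vehicle and 5.65% ± 1.88 (SD, n = 4) in cadmium libraries, which did not pass (exact permutation test, adjusted p = 0.127). Cultured islets held almost no acinar transcripts, 0.0111% ± 0.00330 in vehicle and 0.00959% ± 0.00184 in cadmium cultures (SD, n = 5 each; exact permutation test, adjusted p = 0.497). Ins1 and Ins2, the insulin genes, held 21.2% and 19.95% of counts at 6 weeks (vehicle and cadmium), 12.9% and 13.3% at 18 weeks, and 13.3% and 12.5% in culture, with exact permutation adjusted p-values of 0.138, 0.738 and 0.497. The 10 most abundant genes together held 28.3% and 27.8% at 6 weeks, 29.4% and 28.1% at 18 weeks and 20.8% and 20.04% in culture. None of these passed the exact permutation test (adjusted p = 0.278, 0.738 and 0.497).

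**Figure D1:**
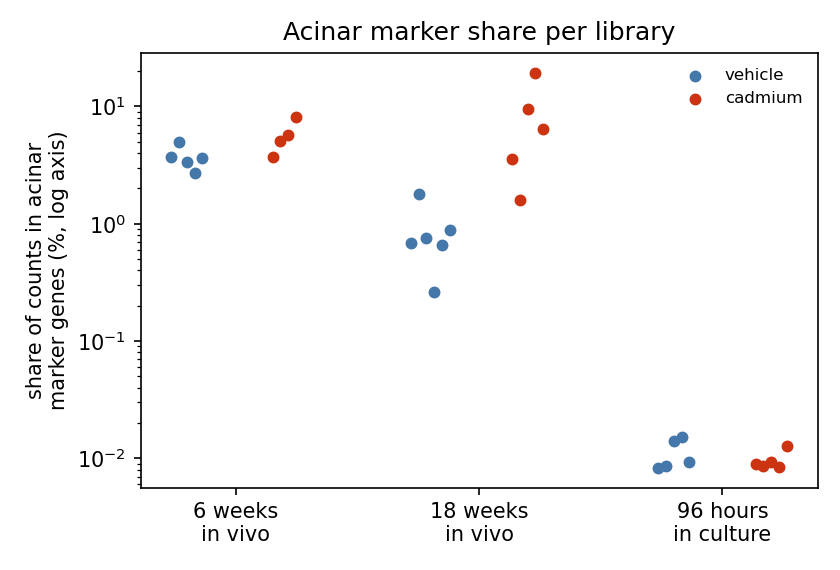
Share of counts in the acinar marker genes (percent, log axis) for each library of the 6 groups, vehicle in blue and cadmium in red, 1 point per library. At 18 weeks the means are 0.844% and 8.08%, and in culture both groups lie near 0.01%.

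After 6 weeks of cadmium no single gene passed the threshold, while digestive enzyme transcripts were on the higher side and immune cell transcripts on the lower side as groups. The 3 genes of smallest p with higher levels began with Gjb1, which encodes the gap junction protein connexin 32, at 0.83 ± 0.12 log2 units. Next were Tnfaip3, a brake on NF-kB signalling, at 0.99 ± 0.16, and Try5, a trypsinogen, at 1.53 ± 0.26, and all were above all 5 vehicle libraries in 4 of 4 cadmium libraries. Their edgeR quasi-likelihood adjusted p-values were 0.596, 0.648 and 0.648. Those with lower levels were the immunoglobulin light chain gene Iglv2 (−3.88 ± 0.88), Cytl1 (−2.31 ± 0.53) and Gmds (−0.16 ± 0.038), each with adjusted p = 0.919. Mt1 and Mt2 encode metallothioneins, small proteins that bind cadmium and zinc and that cadmium induces in many cells. Mt1 stood at 174 ± 45.3 CPM in vehicle (SD, n = 5) and 203 ± 24.8 CPM in cadmium libraries (SD, n = 4), a log2 fold change of 0.22 ± 0.16 (95% interval −0.13 to 0.58, edgeR adjusted p = 0.919). Mt2 was at 0.20 ± 0.23 (adjusted p = 0.936). Of 18080 genes tested with edgeR, 0 passed and 923 had an unadjusted p under 0.05. DESeq2 called 11 (9 higher, 2 lower), and edgeR called 1 without cadmium library 3 and 1 with all 30 libraries in the fit.

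By gene group at 6 weeks, all 34 acinar markers measured were higher, with a median log2 fold change of 0.62 (camera adjusted p = 2.13e-22, and adjusted p = 0.708 with an estimated correlation). None passed over all genes tested, and 23 rose when adjusted over the list alone. Besides Try5 they included Rbpjl, a transcription factor of acinar cells (0.83 ± 0.17), and the trypsinogens Prss3 (1.502 ± 0.34) and Try4 (1.16 ± 0.28), all with adjusted p = 0.919 over all genes. Markers of duct cells lay on the same side in 12 of 15 genes (median 0.14, camera adjusted p = 0.0104, and adjusted p = 0.708 with an estimated correlation). Cftr, the chloride channel of ducts, was at 1.39 ± 0.41. The 24 measured metallothionein and zinc transport genes had a small upward shift (20 higher, median 0.062, 1 past the threshold adjusted over the list alone, camera adjusted p = 0.0159, and adjusted p = 0.708 with an estimated correlation). The zinc importer genes Slc39a4 and Slc39a8 were at 1.54 ± 0.37 and 0.43 ± 0.23. Integrated stress response genes (26 of 29 higher, median 0.12) and clock genes (15 of 17 higher, median 0.10) had camera adjusted p-values of 0.00276 and 0.0101, and adjusted p = 0.736 and 0.708 with an estimated correlation. The acinar share of counts stood at 5.65% in cadmium and 3.70% in vehicle libraries beside these shifts. With that share as a covariate the ductal, metallothionein and integrated stress lists lost their calls (camera adjusted p = 0.161, 0.482 and 0.915), while Mt1 and Mt2 were at 0.20 and 0.17, and clock genes kept theirs (camera adjusted p = 0.00122). Clock genes stood at −0.069, −0.049 and −0.11 in vehicle libraries 1 to 3 and at 0.13 and 0.097 in vehicle 4 and 5 (mean log2 CPM minus the vehicle mean), against 0.025 to 0.21 in cadmium libraries. Ductal markers were at 0.72 and 0.66 in cadmium libraries 2 and 3, and at −0.12 and 0.13 in cadmium 1 and 4. Integrated stress genes were at 0.22 in vehicle library 5, −0.11 to 0.044 in the other vehicle libraries, −0.048 in cadmium 2 and 0.18 to 0.26 in the other cadmium libraries.

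Immune cell markers at 6 weeks lay on the lower side, against a vehicle group whose libraries 1 to 3 stood above libraries 4 and 5. All 22 macrophage and MHC class II markers were lower (median −0.38, camera adjusted p = 1.87e-10, and adjusted p = 0.708 with an estimated correlation), with 1 that fell adjusted over the list alone. Among them C1qa, a complement component made by macrophages, was at −0.39 ± 0.096 and the mannose receptor gene Mrc1 at −1.87 ± 0.56. Mrc1 was at 22.5, 25.7 and 22.8 CPM in vehicle libraries 1 to 3 and at 4.01 and 4.34 CPM in vehicle 4 and 5, near the 3.004 to 5.82 CPM of the cadmium libraries. As a list, macrophage markers stood at 0.43, 0.34 and 0.15 in vehicle 1 to 3 and −0.63 and −0.29 in vehicle 4 and 5 (mean log2 CPM minus the vehicle mean), against −0.998 to −0.198 in cadmium libraries. Lymphocyte markers were lower in 15 of 16 genes (median −0.44, camera adjusted p = 6.79e-05, and adjusted p = 0.736 with an estimated correlation). They included the T cell kinase gene Lck (−0.40 ± 0.16) and Jchain, of antibody-secreting cells (−1.38 ± 0.65). Interferon response genes (30 of 32 lower, median −0.17), class I antigen presentation genes (19 of 19, median −0.14) and proteasome genes (27 of 31, median −0.041) had camera adjusted p-values of 0.000307, 0.00248 and 0.00032, and adjusted p = 0.736, 0.801 and 0.708 with an estimated correlation. Erythroid markers (5 of 5 lower, median −0.75, Hbb-bs at −0.85 ± 0.23), fatty acid oxidation genes (23 of 26 lower, median −0.064) and endothelial markers (15 of 19 lower, median −0.14) had camera adjusted p-values of 0.00248, 0.00248 and 0.00276, and adjusted p = 0.708, 0.708 and 0.776 with an estimated correlation. Stellate and fibroblast markers (20 of 22 lower, median −0.21), ribosomal protein genes (52 of 75 lower, median −0.038) and cell cycle genes (29 of 34 lower, median −0.10) had camera adjusted p-values of 0.00465, 0.0195 and 0.0212, and adjusted p = 0.803, 0.708 and 0.866 with an estimated correlation. The same split held for stellate markers (0.25 to 0.48 in vehicle 1 to 3, −0.71 and −0.48 in vehicle 4 and 5, −0.58 to 0.036 in cadmium libraries) and endothelial markers (0.12 to 0.17, −0.19 and −0.26, −0.23 to −0.11). It held too for interferon response (0.097 to 0.28, −0.36 and −0.17, −0.33 to −0.030) and class I genes (0.073 to 0.34, −0.33 and −0.19, −0.41 to 0.046). Cell cycle genes were at 0.14 and 0.42 in vehicle 3 and 4 and −0.30 to −0.052 in the other vehicle libraries, and cadmium library 3, at 0.31, stood apart from the other cadmium libraries at −0.29 to −0.17. Lymphocyte markers were at 0.68 in cadmium library 2 and −2.44 to −0.46 in the others. In all, 16 of 41 lists were called, 5 up and 11 down, while other splits of the same libraries called a median of 13 lists. Mesothelial markers, tested at 6 weeks only, were not called (3 genes, median −0.20, camera adjusted p = 0.575), and neither were adipocyte markers (4 genes, median −0.10, camera adjusted p = 0.433). Beta cell identity genes (19 of 28 higher, median 0.035) and insulin secretion genes (21 of 30 higher, median 0.034) had camera adjusted p-values of 0.274 and 0.202. Hormone genes did not pass either: Ins1 was at −0.055 ± 0.066, Ins2 at −0.063 ± 0.075, Gcg (glucagon) at 0.11 ± 0.070 and Ppy (pancreatic polypeptide) at 0.11 ± 0.15.

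After 18 weeks of cadmium 72 genes rose and 3 fell, and most of the strongest rises were genes of digestive enzymes and their helpers. The trypsinogen gene Try5 rose from 177 ± 101 CPM (SD, n = 6) to 4050 ± 3424 CPM (SD, n = 5), a fold of 22.8 (4.51 ± 0.62 log2 units). Try4 went from 322 to 5888 CPM (4.19 ± 0.66). Chymotrypsinogen gene Ctrb1 rose by 3.77 ± 0.61, from 586 to 7997 CPM, and Prss2, another trypsinogen, by 3.68 ± 0.62, from 558.5 to 7160 CPM. Spink1, an inhibitor of trypsin, rose by 3.71 ± 0.59, and Sycn, a protein of zymogen granules, by 3.77 ± 0.65. The phospholipase gene Pla2g1b rose by 3.67 ± 0.66 and Pdia2, a protein folding enzyme of the exocrine pancreas, by 4.12 ± 0.81. The edgeR adjusted p was 0.0376 for each of these but Pdia2, at 0.0473. Try5, Try4, Ctrb1, Sycn and Pla2g1b lay above all vehicle libraries in 5 of 5 cadmium libraries and Spink1, Prss2 and Pdia2 in 4 of 5. The falling genes were Sim1, a transcription factor gene (−0.46 ± 0.084, from 31.7 to 22.9 CPM, below all vehicle libraries in 5 of 5, adjusted p = 0.0376), and the predicted genes Gm37755 (−0.79 ± 0.14) and Gm26945 (−0.65 ± 0.12). Both predicted genes lie outside the naming rule and were chosen after their values were seen. Next by p were Hapln1 (−0.52 ± 0.11, adjusted p = 0.0566) and Uggt2 (−0.34 ± 0.074, adjusted p = 0.0701), which did not pass.

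Of 20911 genes tested at 18 weeks, 3804 had an unadjusted p under 0.05, and the lowest edgeR adjusted p was 0.0376, so the calls lay close to the threshold. Leaving out vehicle library 1, 3, 4, 5 or 6 or cadmium library 3 left 0 calls. Without cadmium library 4 there were 2, and leaving out vehicle library 2 or cadmium library 1, 2 or 5 gave 135, 195, 196 and 318. DESeq2 called 765 genes (550 higher, 215 lower), edgeR without a count filter 140 and edgeR on all 30 libraries 2496. Called genes numbered 0 by edgeR with the acinar share as a covariate, with the 3 libraries of lowest depth left out or with a surrogate variable, and 0 by limma-voom with library weights. The cadmium libraries held 8.08% acinar transcripts on average against 0.844%, and with acinar and Reg genes left out before scaling 0 of the remaining genes passed. The folds were hardly changed by leaving these genes out, for example Tff2 at 3.20 and Ldha at 1.07, each with an edgeR adjusted p of 0.0536.

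**Figure D2:**
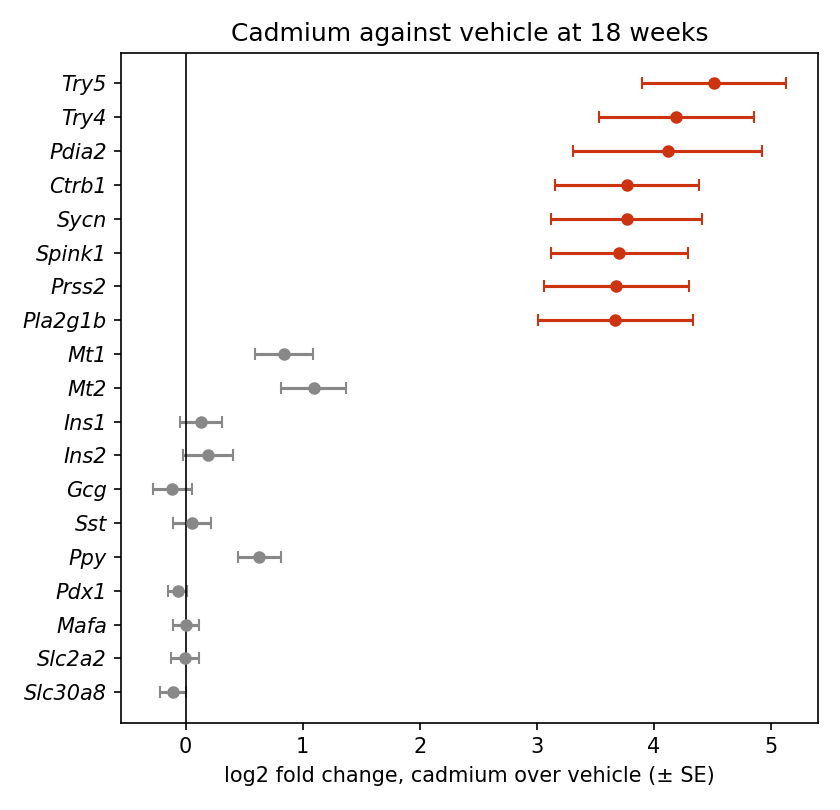
Log2 fold change of cadmium over vehicle at 18 weeks (horizontal axis, bars are ± SE, n = 6 vehicle and 5 cadmium libraries) for 8 genes that rose (red) and for panel genes that did not pass (grey). Try5 is at 4.51, Mt1 at 0.84 and Ins2 at 0.19.

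Metallothionein transcripts were higher at 18 weeks without passing. Mt1 stood at 137 ± 50.5 CPM in vehicle (SD, n = 6) and 245 ± 78.8 CPM in cadmium libraries (SD, n = 5), a log2 fold change of 0.84 ± 0.25 (edgeR adjusted p = 0.142), with 4 of 5 cadmium libraries above all vehicle libraries. Mt2 went from 2.77 to 6.01 CPM (1.09 ± 0.28, edgeR adjusted p = 0.104, DESeq2 adjusted p = 0.00553). In a fit of all 30 libraries the edgeR adjusted p of Mt1 was 0.00667 and that of Mt2 0.00678. That fit shares its estimate of spread between settings, and in it Mt1 lost its call in culture. With the acinar share as a covariate Mt1 was at 0.66 ± 0.47 and Mt2 at 0.82 ± 0.51 (edgeR adjusted p = 0.994 for both). With 1 surrogate variable the edgeR adjusted p was 0.154 and 0.147, and by limma-voom with library weights it was 0.0927 and 0.0919. The zinc exporter gene Slc30a1, a sensitive target of metal-responsive transcription, was at 0.16 ± 0.090 (adjusted p = 0.347), and the oxidative stress genes Hmox1 and Nqo1 were at 0.22 ± 0.25 and 0.062 ± 0.15. The 23 measured metallothionein and zinc transport genes (1 rose, 7 rose adjusted over the list alone, median 0.093) had a camera adjusted p of 0.0246, and adjusted p = 0.319 with an estimated correlation. Its called member was Slc39a5, a zinc importer gene of acinar cells and other epithelia (2.80 ± 0.52, edgeR adjusted p = 0.0376), and 4 of 5 cadmium libraries had it above all vehicle libraries. With the acinar share as a covariate Slc39a5 was at −0.23. For Slc39a5, as for Mt1 and Mt2, that fit decides nothing at 18 weeks, since the share carries most of the difference between the groups.

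Endocrine transcripts did not pass at 18 weeks. Ins1 was at 0.13 ± 0.18 (edgeR adjusted p = 0.715), Ins2 at 0.19 ± 0.21 (0.647), Gcg at −0.11 ± 0.17, and Sst (somatostatin) at 0.053 ± 0.16. The beta cell transcription factor genes Pdx1 and Mafa were at −0.066 ± 0.081 and 0.00065 ± 0.11. The glucose transporter gene Slc2a2 and the granule zinc transporter gene Slc30a8 were at −0.0045 ± 0.12 and −0.11 ± 0.11. Ppy, the pancreatic polypeptide gene, was highest of the panel hormones at 0.63 ± 0.18 (1297 to 2008 CPM, 4 of 5 above all vehicle libraries, edgeR adjusted p = 0.142, DESeq2 adjusted p = 0.0193). None of 29 beta cell identity genes passed (median −0.019, camera adjusted p = 0.501). The same held for 30 insulin secretion genes (median 0.00096 with a downward test, camera adjusted p = 0.972) and 21 granule genes (median −0.049, camera adjusted p = 0.275). It held too for 10 alpha cell markers (median 0.036, 1 past the threshold adjusted over the list alone, camera adjusted p = 0.687) and 8 delta and PP markers (median 0.054, 1 past the threshold adjusted over the list alone, camera adjusted p = 0.208).

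The gene groups at 18 weeks moved mostly up, with 26 of 40 lists called, 25 up and 1 down. Of 34 acinar markers 27 rose and 32 rose adjusted over the list alone (median 3.43, camera adjusted p = 2.46e-29, and adjusted p = 0.319 with an estimated correlation). Of 14 ductal markers 1 rose, Tff2, a secreted trefoil factor (3.21 ± 0.57, adjusted p = 0.0376), and 11 rose adjusted over the list alone (median 0.56, camera adjusted p = 2.45e-07, and adjusted p = 0.319 with an estimated correlation). With the acinar share as a covariate Tff2 was at −0.19, but that fit decides nothing here, since the share carries most of the difference between the groups. The keratin gene Krt19 missed the threshold (3.14 ± 0.64, adjusted p = 0.0566). Among 22 macrophage and MHC class II markers, such as Tyrobp (0.57 ± 0.13) and H2-Aa (0.53 ± 0.14), 0 passed over all genes by edgeR and 12 rose adjusted over the list alone (median 0.40, camera adjusted p = 1.17e-07, and adjusted p = 0.319 with an estimated correlation). Stellate and fibroblast markers (16 of 21 rose adjusted over the list alone, median 1.12) included Col1a2, a collagen chain (1.18 ± 0.34), and Sparc (0.37 ± 0.10). The camera adjusted p of this list was 2.45e-07, and adjusted p = 0.329 with an estimated correlation. Lymphocyte markers (10 of 15 adjusted over the list alone, median 2.56), endothelial markers (0 of 19, median 0.20) and Schwann markers (0 of 10, median 0.57) had camera adjusted p-values of 0.00218, 0.00386 and 0.0165, and adjusted p = 0.47, 0.329 and 0.41 with an estimated correlation. Lymphocyte markers stood high in cadmium libraries 2, 3 and 4 (3.39, 3.69 and 1.45, mean log2 CPM minus the vehicle mean) and in vehicle library 4 (2.06), and cadmium libraries 1 and 5 were at −1.07 and −0.59. Macrophage and stellate markers were also highest in cadmium 2 to 4 (0.51 to 0.75 and 1.26 to 1.94), with cadmium 1 and 5 at 0.16 and 0.075 and at 0.19 and 0.18. The Reg family, secreted proteins of the exocrine pancreas and of stressed islets, had a median of 2.10 with 2 of 6 genes past the threshold adjusted over the list alone (camera adjusted p = 0.000954, and adjusted p = 0.329 with an estimated correlation). Reg1 was at 2.99 ± 0.69 (adjusted p = 0.0831). Erythroid markers were the list on the lower side (median −0.75, Alas2 at −0.66 ± 0.16, camera adjusted p = 0.0246, and adjusted p = 0.421 with an estimated correlation).

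Ribosomal protein genes were higher in 78 of 79 members at 18 weeks (60 rose adjusted over the list alone, median 0.39, camera adjusted p = 2.07e-21, and adjusted p = 0.329 with an estimated correlation). Nuclear genes of oxidative phosphorylation were higher in 51 of 57 (16 rose adjusted over the list alone, median 0.21), class I antigen presentation genes in 18 of 19 (13 adjusted over the list alone, median 0.38) and glycolysis genes in 22 of 22 (7 adjusted over the list alone, median 0.22). Their camera adjusted p-values were 1.17e-07, 1.99e-07 and 1.07e-06, and adjusted p = 0.347, 0.319 and 0.324 with an estimated correlation. Ldha, the lactate dehydrogenase subunit that beta cells keep low, rose by 1.07 ± 0.20 (7.03 to 14.7 CPM, edgeR adjusted p = 0.0376). It was the called member of the glycolysis list and of the 20 disallowed and dedifferentiation genes, of which 13 rose adjusted over the list alone (median 0.82, camera adjusted p = 4.75e-08, and adjusted p = 0.322 with an estimated correlation). Gsta4, a glutathione transferase, rose by 1.72 ± 0.31 and Stc2, a secreted stress-induced glycoprotein, by 3.001 ± 0.55 (edgeR adjusted p = 0.0376 for both). Their lists, NRF2 targets with glutathione genes (1 of 36 rose, 8 adjusted over the list alone, median 0.17) and the integrated stress response (1 of 29, 3 adjusted over the list alone, median 0.16), had camera adjusted p-values of 3.93e-05 and 0.0158, and adjusted p = 0.322 and 0.47 with an estimated correlation. All these shifts stood beside the acinar share of 8.08% against 0.844%. Cadmium library 5 did not share the rise of ribosomal protein and oxidative phosphorylation genes (−0.068 and −0.035, mean log2 CPM minus the vehicle mean), and the other cadmium libraries stood at 0.27 to 0.62 and 0.098 to 0.31.

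Further lists called upward at 18 weeks had 0 members past the threshold over all genes by edgeR. Interferon response (2 of 32 rose adjusted over the list alone, median 0.30), inflammation (7 of 22, median 0.71) and iron and copper handling genes (8 of 23 rose and 2 fell, median 0.21) had camera adjusted p-values of 4.35e-05, 0.000442 and 0.0044, and adjusted p = 0.322, 0.329 and 0.319 with an estimated correlation. Antioxidant enzymes (6 of 22 adjusted over the list alone, median 0.11), fatty acid synthesis (3 of 20, median 0.12) and fatty acid oxidation genes (1 of 26, median 0.10) had camera adjusted p-values of 0.0127, 0.0039 and 0.0116, and adjusted p = 0.329 for all of them with an estimated correlation. Prdx4, a peroxiredoxin of the endoplasmic reticulum, was at 0.98 ± 0.27. Proteasome (median 0.093), autophagy (median 0.081) and glucocorticoid target genes (1 of 11 adjusted over the list alone, median 0.28) had camera adjusted p-values of 0.0044, 0.0246 and 0.036, and adjusted p = 0.457, 0.329 and 0.421 with an estimated correlation. Lists that were not called included the unfolded protein response (camera adjusted p = 0.481), heat shock (0.687), cell cycle (0.0639), p53 targets (0.0726) and hypoxia (0.132). Others were cholesterol biosynthesis (camera adjusted p = 0.0822), the clock (0.887), adipocyte markers (0.377) and immediate early genes, of which 23 of 24 were higher (median 0.47, camera adjusted p = 0.267).

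In islets cultured with cadmium for 96 hours the metallothionein gene Mt1 rose in every cadmium library. Its level was 203 ± 22.02 CPM in vehicle and 313 ± 27.3 CPM in cadmium cultures (SD, n = 5 each), a fold of 1.55 (0.63 ± 0.071 log2 units, 95% interval 0.48 to 0.78, edgeR adjusted p = 0.00386). It was the single call among 16743 genes. Mt2 was at 0.77 ± 0.20 from 1.90 to 3.24 CPM, Slc30a1 at 0.16 ± 0.046 and Sphk1, which makes sphingosine 1-phosphate, at 1.02 ± 0.21, all with edgeR adjusted p = 0.888 in the fit without pairs. In that fit 920 genes had an unadjusted p under 0.05 and DESeq2 called 1 gene. Without a count filter edgeR called 7, edgeR on all 30 libraries called 0, and leaving out cadmium library 5 gave 2.

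With the replicate number as a block, 211 genes rose and 12 fell among 17702 tested in culture. Mt1 kept its size (0.63 ± 0.041, edgeR adjusted p = 2.36e-06), Mt2 rose by 0.77 ± 0.15 (adjusted p = 0.0171, DESeq2 with the block adjusted p = 0.0586, higher in 5 of 5 pairs), and Slc30a1 missed the threshold (0.16 ± 0.038, adjusted p = 0.0531, 5 of 5 pairs). The matrix proteins Postn (158 to 233 CPM, 0.55 ± 0.050, adjusted p = 6.23e-05), Sparc (0.44 ± 0.057, adjusted p = 0.000988), Col6a1 (0.48 ± 0.069, adjusted p = 0.00189) and Dcn (0.60 ± 0.086, adjusted p = 0.00191) rose in 5 of 5 pairs. The largest rises were those of the matrix metalloprotease gene Mmp7 (2.44 ± 0.44, 4 of 5 pairs, adjusted p = 0.0101), the neuropeptide gene Vip (1.34 ± 0.29, 4 of 5 pairs, adjusted p = 0.0339), Smoc2 (1.34 ± 0.29, adjusted p = 0.0326), and Mfap5 (1.22 ± 0.22, adjusted p = 0.00932). Next came Itm2a (1.19 ± 0.17, adjusted p = 0.00222), the activin subunit gene Inhba (1.03 ± 0.13, adjusted p = 0.000742), the Wnt inhibitor gene Sfrp1 (1.01 ± 0.14, adjusted p = 0.00181) and Sphk1 (1.00 ± 0.16, adjusted p = 0.00373). Levels were low for Mmp7, at 0 to 0.8636 CPM in vehicle and 0.07914 to 4.505 CPM in cadmium cultures, with 0 and 0.2779 CPM in pair 4. Smoc2 was at 0.08004 to 1.217 CPM in vehicle and 0.831 to 2.111 CPM in cadmium cultures. The folds of these 2 genes start from few counts. Ppy fell by 0.27 log2 units (SE 0.052, adjusted p = 0.0165, lower in each pair but almost level in pair 3, at 2790 CPM in vehicle and 2784 CPM in cadmium). H2-Aa, an MHC class II chain, fell by 0.49 (SE 0.11, adjusted p = 0.0447) and L3mbtl2, a chromatin protein gene, by 0.22. Pappa2, a protease of insulin-like growth factor binding proteins, fell by 0.16, Rnf216 by 0.16, Pcdh15 by 0.15 and Tox3 by 0.14 (edgeR adjusted p = 0.0157 to 0.0453 for L3mbtl2 and the genes after it).

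The blocked count in culture rested partly on single pairs. Leaving out pair 1 gave 100 calls and pair 2 gave 121, while pairs 3, 4 and 5 gave 184, 155 and 269. Without pair 2 or 3 the edgeR adjusted p of Mt2 was 0.0878 and 0.0858. Without pair 1 or 2 that of Ppy was 0.11 and 0.0768, and without pair 2 that of Mmp7 was 0.0891. DESeq2 with the block called 117 genes (110 higher, 7 lower). Among the genes named it did not call Mt2, Mmp7 (adjusted p = 0.503), Vip (0.507), Mfap5 (0.113), Rest (0.0826), H2-Aa (0.186), L3mbtl2 (0.121), Rnf216 (0.139), Pcdh15 (0.175) or Tox3 (0.159). In simulated data 10.6% of blocked calls were false.

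**Figure D3:**
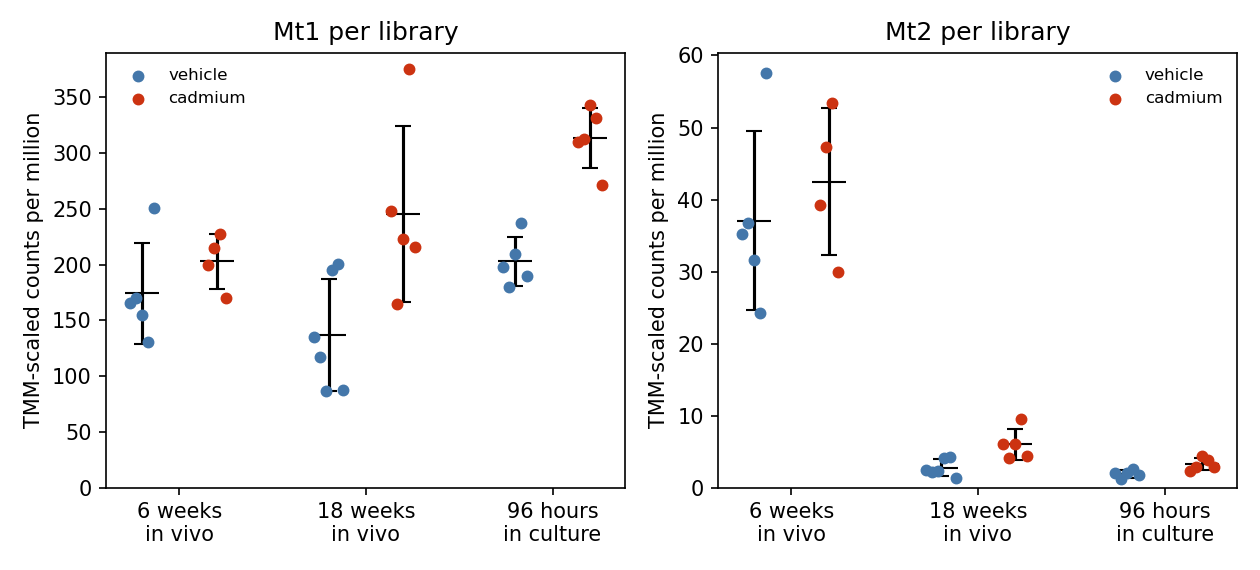
Levels of Mt1 (left) and Mt2 (right) per library in CPM, scaled within each comparison, with vehicle in blue, cadmium in red and bars for mean ± SD. In culture all 5 cadmium libraries lie above the vehicle libraries for Mt1 (203 and 313 CPM on average), and at 18 weeks 4 of 5 do.

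**Figure D4:**
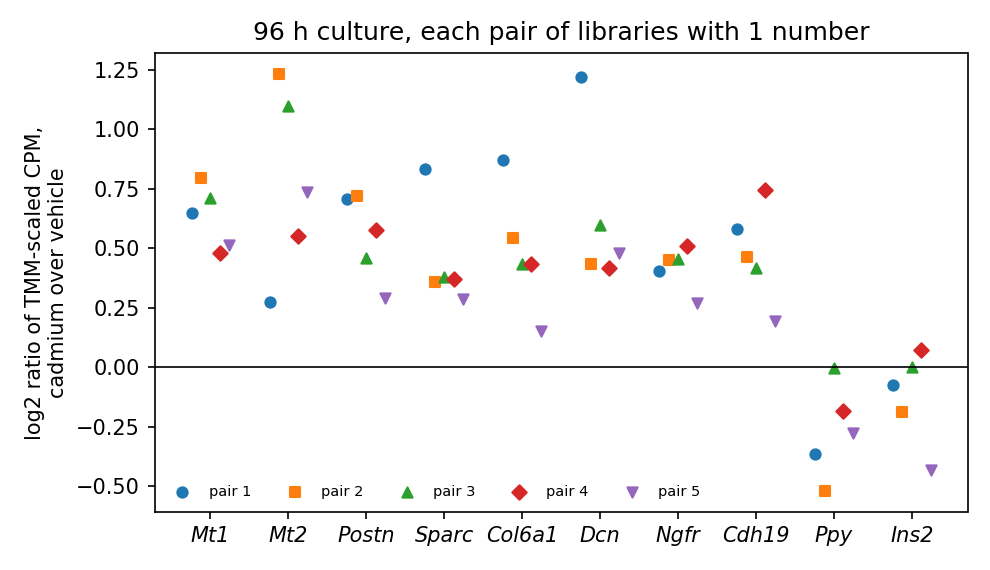
Log2 ratio of CPM, cadmium over vehicle, in each of the 5 culture pairs (1 symbol per pair) for 10 genes. Mt1, Mt2, Postn, Sparc, Col6a1, Dcn, Ngfr and Cdh19 lie above 0 in 5 of 5 pairs and Ppy below 0 in all 5, though almost at 0 in pair 3.

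By gene group in culture, stellate and fibroblast markers had the smallest camera p in both fits. Without pairs 0 of 21 passed by edgeR and 2 rose adjusted over the list alone (camera adjusted p = 7.11e-09, and adjusted p = 0.644 with an estimated correlation). With the block 16 of 21 rose and 17 rose adjusted over the list alone (median 0.44, camera adjusted p = 4.88e-14, and adjusted p = 0.271 with an estimated correlation). Schwann cell markers, for example the neurotrophin receptor gene Ngfr (0.42 ± 0.049) and the cadherin gene Cdh19 (0.47 ± 0.071), were not called without pairs (camera adjusted p = 0.0688). With pairs 2 of 10 rose and 6 rose adjusted over the list alone (median 0.21, camera adjusted p = 0.000715, and adjusted p = 0.271 with an estimated correlation). Disallowed and dedifferentiation genes were called in both fits (median 0.31 and 0.26, camera adjusted p = 1.29e-06 and 3.69e-07, and adjusted p = 0.644 and 0.271 with an estimated correlation). With the block 3 of 21 rose, among them Rest, a repressor of neuronal and endocrine genes (0.47 ± 0.087, adjusted p = 0.0126), and Igfbp4 (0.77 ± 0.16, adjusted p = 0.0287). Endothelial markers (median 0.18) and ductal markers (median 0.15, 1 of 13 rose) had camera adjusted p-values of 0.000715 and 0.00207 with the block and 0.0249 and 0.000735 without, and adjusted p = 0.475 for both with the block and an estimated correlation. By pair, the mean log2 difference was 0.29 to 0.77 for stellate markers and 0.13 to 0.33 for Schwann markers. Endothelial markers were at 0.56 in pair 1 and 0.0078 to 0.18 in the others, and ductal markers at −0.31 in pair 3 and 0.42 to 0.70 in the others. Disallowed genes were at 0.54 and 0.50 in pairs 1 and 2 and 0.036, 0.15 and 0.23 in pairs 3 to 5. Glycolysis and hypoxia genes were at 0.31 and 0.68, and at 0.17 and 0.63, in pairs 1 and 2, and below 0 in the others. Macrophage and MHC class II markers did not move with them (median −0.052 with the block, 1 fell, camera adjusted p = 0.0502), and neither did 5 lymphocyte markers (camera adjusted p = 0.739).

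Interferon response (26 of 29 higher, median 0.092), inflammation (23 of 28 higher, median 0.15) and class I antigen presentation genes (15 of 19 higher, median 0.068, B2m rose by 0.20 ± 0.038) had camera adjusted p-values of 0.000282, 0.000715 and 0.00548 in culture with the block, and adjusted p = 0.271 for each with an estimated correlation. Inflammation genes were at −0.068 in pair 3 (11 of 28 higher) and 0.12 to 0.44 in the other pairs. Among 26 p53 target genes 1 rose, the death-promoting Pmaip1 (0.71 ± 0.12, edgeR adjusted p = 0.00575), with a list median of 0.038 (camera adjusted p = 0.0364, and adjusted p = 0.271 with an estimated correlation). Lower lists had 0 members called by edgeR in either fit, apart from Ppy. With the block they were the unfolded protein response (27 of 29 lower, median −0.045, camera adjusted p = 0.00058), beta cell identity (25 of 28 lower, median −0.044, camera adjusted p = 0.00215), granule biogenesis (17 of 21 lower, median −0.055, camera adjusted p = 0.00349) and oxidative phosphorylation (51 of 57 lower, median −0.036, camera adjusted p = 0.000715). Their estimated correlations gave adjusted p = 0.271, 0.271, 0.374 and 0.475. Called with the block alone were ribosomal proteins (62 of 78 lower, median −0.028, camera adjusted p = 0.0145), delta and PP markers (1 of 7 fell, median −0.092, camera adjusted p = 0.00954) and acinar markers (17 of 19 lower, median −0.77, camera adjusted p = 0.0295), with adjusted p = 0.797, 0.453 and 0.63 with an estimated correlation. These shifts were not shared by all pairs: from pair 1 to 5 the mean log2 difference was −0.021, −0.053, 0.020, 0.058 and −0.12 for ribosomal proteins and 1.27, −0.16, −2.34, −3.32 and 1.57 for acinar markers. For oxidative phosphorylation genes it was −0.065, −0.037, −0.014, 0.0085 and −0.095. Beta cell identity genes were at −0.105 and −0.086 in pairs 1 and 2 and at −0.023, −0.027 and −0.0031 in pairs 3 to 5, where 13, 10 and 12 of 28 were higher. In pair 2, 16 of 29 unfolded protein response genes were higher, and in pair 4, 13 of 21 granule genes. Culture cadmium library 5, of the pair with the largest falls in ribosomal and oxidative phosphorylation genes, held 10.5% insulin transcripts and 17.8% in its 10 most abundant genes. The 12 lists called without pairs became 16 with them. Panel genes of beta cells did not pass in the blocked fit, with Ins1 at −0.083 ± 0.044, Ins2 at −0.12 ± 0.053 (edgeR adjusted p = 0.442), Slc2a2 at −0.11 ± 0.032 (0.167) and Mafa at −0.013 ± 0.093. The metallothionein and zinc list as a whole was not called (2 of 23 rose with the block, camera adjusted p = 0.501), nor were NRF2 targets (0.842), antioxidant enzymes (0.809), heat shock (0.131), insulin secretion (0.0599) or the integrated stress response (0.991).

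Differences of the cadmium effect between settings were called for 382 genes between the 2 times in vivo, and for 0 in a fit of those 4 groups alone. Each setting was compared through its own vehicle group, and the 18 week libraries also differed in kind from the others, with Rn7sk at 1.91 to 4.97% of counts against at most 0.00048%. The cadmium effect differed between 18 and 6 weeks for 382 of 22721 genes, 204 more positive and 178 more negative at 18 weeks (edgeR, 4838 with an unadjusted p under 0.05). The fit of all 6 groups shares its estimate of spread between settings. Its biological coefficient of variation was 0.158, against 0.212 at 18 weeks fitted alone, so these counts may be too high. Cd163, a scavenger receptor gene of macrophages, was at 1.20 after 18 weeks and −2.42 after 6 weeks (difference 3.60 ± 0.80, adjusted p = 0.0329, and 0.155 in the fit of the 4 in vivo groups). Pdia2 differed by 3.52 ± 0.80 (adjusted p = 0.034) and Sycn by 3.21 ± 0.68 (adjusted p = 0.0326). Muc6, a secreted mucin gene, was at 0.086 after 18 weeks and 4.92 after 6 weeks (difference −4.82 ± 0.97, adjusted p = 0.0305). The NF-kB subunit gene Rel was at −0.24 and 0.45 (difference −0.71 ± 0.15). Zbtb20, a repressor gene active in beta cells, was at −0.40 and 0.29 (difference −0.70 ± 0.18) and Ireb2, a sensor of iron, at −0.55 and 0.11 (difference −0.67 ± 0.16). The metallothionein genes did not differ past the threshold (Mt1 by 0.61 ± 0.29, adjusted p = 0.221, Mt2 by 0.88 ± 0.34, adjusted p = 0.139). Removing single libraries moved the count widely. Without 6 week vehicle 1 to 5 it was 2, 0, 0, 895 and 403, and without 6 week cadmium 1 to 4 it was 18, 109, 0 and 157. Without 18 week vehicle 1 to 6 it was 98, 398, 251, 1322, 617 and 9, and without 18 week cadmium 1 to 5 it was 902, 586, 2, 0 and 1694. DESeq2 called 1385, edgeR without a count filter called 192 and edgeR on the 4 in vivo groups called 0. Without the 3 libraries of lowest depth edgeR called more genes than in any of these fits.

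Between culture and 18 weeks 4 genes differed (edgeR, 2995 with an unadjusted p under 0.05, lowest adjusted p = 0.0499). Cela1, an elastase gene of acinar cells, was at −0.17 in culture and 3.36 at 18 weeks (difference −3.53 ± 0.63). Dusp26, a phosphatase gene, was at −0.087 and 0.78 (difference −0.86 ± 0.15) and the splicing factor gene Prpf19 at −0.040 and 0.38 (difference −0.42 ± 0.077). The predicted gene Gm37755, outside the naming rule and chosen after its values were seen, was more positive in culture. Mt1 differed by −0.21 ± 0.28 (adjusted p = 0.792) and Mt2 by −0.31 ± 0.40 (adjusted p = 0.780). The count was 0 without 18 week vehicle 1, 3 or 6, 18 week cadmium 3 or 4, or any culture library but cadmium 5, which gave 12. It was 13 without 18 week vehicle 2, and 58 and 358 without 18 week cadmium 2 and 5. DESeq2 called 196 genes, edgeR without the 3 libraries of lowest depth called 1057, and edgeR with the culture pairs as a block called 0. Between culture and 6 weeks edgeR called 0 genes with 760 at an unadjusted p under 0.05 and DESeq2 called 3. Without 6 week cadmium library 1 or 2 edgeR called 1. Mt1 differed by 0.40 ± 0.29 and Mt2 by 0.56 ± 0.38 there.

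In the fits without pairs, 0 calls at 6 weeks and 1 in culture left almost no room for shared calls, and none were shared. With the blocked culture fit, 2 of the genes that rose at 18 weeks also rose in culture, Lgals1 and Stc2, out of 42 and 204 called among 17244 genes tested in both (0.497 expected, exact hypergeometric test, p = 0.0882). Lgals1 lies outside the naming rule and was chosen after its values were seen. DESeq2 called 5 genes as higher at both 6 and 18 weeks. Across genes, which are not independent replicates, the fold changes correlated at r = 0.0258 for 6 against 18 weeks, −0.132 for 6 weeks against culture and 0.194 for 18 weeks against culture.

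Vehicle islets at 18 weeks differed from vehicle islets at 6 weeks in most genes, with transcripts that lack a poly(A) tail far higher. The small nuclear RNA Rn7sk went from 1.51 ± 0.201 CPM (SD, n = 5) to 30550 ± 8765 CPM (SD, n = 6) and the histone gene Hist1h4n from 0.00838 to 27.7 CPM. Rn7s6, Rn7s1 and Rn7s2, RNAs of the signal recognition particle, were at 0 counts in all 6 week vehicle libraries and at 69.2, 7.36 and 4.21 CPM at 18 weeks. Saa3, an acute phase gene, went from 26.7 ± 18.4 to 0.00311 CPM, Alox15, a lipoxygenase gene, from 11.4 to 0.00592 CPM and the immunoglobulin segment Ighv7-3 from 7.16 to 0.00311 CPM. Igkv14-126 and Igkv12-89 went from 6.06 and 4.98 CPM to 0. Of 20551 genes 7376 rose and 7380 fell by edgeR (71.8%), RLE scaling gave 7974 and 6773, and DESeq2 10489 and 7341. Rn7sk held 1.91 to 4.97% of counts in every 18 week library, treated or not, and at most 0.00048% in every other library, so the difference between these times cannot be told apart from a difference in library preparation.

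Positions of the main genes on build mm10 are as follows. Mt1 (ENSMUSG00000031765) lies on chromosome 8 from 94179082 to 94180327 and Mt2 (ENSMUSG00000031762) beside it from 94172664 to 94173568, both on the plus strand. Try5 (ENSMUSG00000036938) lies on chromosome 6 from 41311233 to 41316841 and Prss2 (ENSMUSG00000057163) on the same chromosome from 41521787 to 41525079. Ctrb1 (ENSMUSG00000031957) lies on chromosome 8 from 111686519 to 111691010, Sim1 (ENSMUSG00000019913) on chromosome 10 from 50894754 to 50989152, Postn (ENSMUSG00000027750) on chromosome 3 from 54361109 to 54391037 and Ppy (ENSMUSG00000017316) on chromosome 11 from 102099930 to 102101319. All are protein-coding, and their values are counts over whole genes.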

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

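The tests of exocrine carry-over, stromal cells and length or GC content were set out before their results were seen. The rules applied to them added conditions on spread to the limits written beforehand. The tests of depth, acinar cells in culture, endocrine share, single culture pairs and other splits of the libraries were tests chosen after the results they bear on. Bootstrap intervals in this section draw genes at random, not libraries. Genes that move together are not independent, so these intervals do not measure the spread between libraries.

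The cadmium effect differed between times for 382 genes (18 against 6 weeks) and between culture and 18 weeks for 4, each by a test of the difference in 1 fit of all 30 libraries. That fit shares its estimate of spread between settings. Its biological coefficient of variation was 0.158, against 0.212 at 18 weeks, 0.133 at 6 weeks and 0.0686 in culture fitted alone. Its spread may be too low for 18 weeks and both counts too high. The count of 382 was 0 in the fit of the 4 in vivo groups and 0 to 1694 with a library left out. The count of 4 was 0 with the culture pairs as a block and 0 to 358 with a library left out. Single libraries that stood apart from the rest of their group were counted next. Of these, 24 of 268 groups of values held one, where chance gives about 1 in 20 groups, or 13.4. By depth, 18 week cadmium library 5 had 21573301 counts against 46814618 to 51852364 in the others, and its 10 most abundant genes held 23.2% of counts against 28.67 to 30.14%. Culture cadmium library 5 had an acinar share of 0.01282% (others 0.008385 to 0.0093%) and culture vehicle library 1 an insulin share of 13.74% (others 13.05 to 13.18%). An erythroid share stood apart in 18 week vehicle library 4, at 0.01367% (others 0.0029 to 0.004628%). The transcript CT010467.1 held 14.06% of counts in 18 week vehicle library 6 (others 0.1475 to 4.554%), 0.1104% in 6 week vehicle library 2 (others 0.1425 to 0.1553%) and 0.1804% in culture vehicle library 1 (others 0.114 to 0.123%).

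Among named genes at 6 weeks, Ppy was at 3380 CPM in vehicle library 2 (others 1931 to 2289), Gmds at 24.26 CPM in cadmium library 4 (25.42 to 25.6) and the interferon regulator gene Irf1 at 61.81 CPM in the same library (44.07 to 46.66). Cftr was at 0.9391 CPM in 6 week vehicle library 5 (others 0.4538 to 0.5116) and 3.16 CPM in 6 week cadmium library 3 (0.715 to 1.133). At 18 weeks vehicle library 2 held the highest Krt19 (2.464 CPM, others 0.2734 to 0.8064), Stc2 (0.5417 CPM, others 0.06803 to 0.15) and Col1a2 (11.22 CPM, others 4.632 to 6.158) of its group. Cadmium library 4 of that time held Col1a2 at 30.41 CPM (7.132 to 13.16). In culture Mafa was at 608 CPM in vehicle library 1 (420 to 467.7) and 649.2 CPM in cadmium library 5 (398.9 to 469.9). Slc2a2 was at 1269 CPM in vehicle library 1 (1062 to 1105) and Rnf216 at 50.93 CPM in cadmium library 5 (53.22 to 54.01). H2-Aa was at 7.839 CPM in culture vehicle library 2 (4.868 to 5.416), and Col6a1 and Cdh19 were at 89.36 and 23.06 CPM in culture cadmium library 2 (43.36 to 55.47 and 12.03 to 14.67).

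The rise of 72 genes at 18 weeks held 27 of the acinar list and 45 others, with a median log2 fold change of 3.18. Lower depth of 3 libraries is argued against as the cause, since without them the median was 3.13, 98.2% of its size (95% bootstrap interval over genes 2.91 to 3.28). The lowest edgeR adjusted p was then 0.0624, though, and the median SE went from 0.576 to 0.722. Exocrine tissue carried into the islet preparations is a candidate explanation, since in the 6 week libraries, within groups, the 45 genes outside the acinar list followed the acinar share with a median slope of 0.654 (bootstrap interval 0.476 to 0.864), against −0.00153 for all genes tested and 1.01 for the acinar list, and the acinar share itself varied there over 1.14 log2 units. A fit with the acinar share as a covariate decides nothing at 18 weeks, since 27 of the 72 genes make up the share and the share carries most of the difference between the groups (the median of the 45 other genes went from 2.76 (median SE 0.501) to 0.254 (median SE 0.346), which ended the calls). Whether cadmium itself changed the acinar tissue or its attachment to islets stays open and untested, as does a rise of these genes inside islet cells (0 of the 35 acinar symbols stand in another list).

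The rise of Mt1 in culture (block value 0.629 ± 0.0411) is argued not to come from acinar cells, whose 10 measured markers had a median log2 fold change of −0.191 (bootstrap interval −0.927 to −0.0789), while the whole acinar list summed to 111 CPM in vehicle and 95.9 CPM in cadmium cultures. A larger share of stromal cells in the cadmium cultures stays open as a part of it. With the stellate and fibroblast score beside the block, Mt1 was at 0.533 ± 0.104 (84.8% of its size, unadjusted p = 8.65e-05 by edgeR) and Mt2 at 1.15 (unadjusted p = 0.00632). The Mt1 values met the limit written beforehand for arguing against stromal cells. The rule applied also asked for a margin of the SE, which they did not meet. Besides, the score moves with treatment, 3 residual degrees of freedom are left and the adjusted p of Mt1 was 0.766 with 0 genes called. An induction of metallothioneins by cadmium within the cells, the biological explanation the design offers, may hold and could not be separated from it by this fit.

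Stellate and fibroblast markers rose in culture with a median of 0.442 with the block (interval 0.316 to 0.58). A lower share of endocrine cells alone would raise macrophage markers alike. These were at −0.0518, a difference of 0.494 (bootstrap interval over genes 0.342 to 0.652). The test cannot decide it, since it rests on 1 control list that may change for other reasons. With the block the Schwann, endothelial and ductal lists were called up, and beta cell identity and granule genes down. Removing the trend on gene length and GC content over 14700 genes left a median of 0.453 for the 21 markers (102% of its size, interval 98.8 to 104). The trend itself was small (SD 0.00797 log2 units over these genes), so there was little to remove. Leaving out each pair gave a lowest median of 0.356 without pair 1 (interval 0.329 to 0.442) and 0.467, 0.462, 0.487 and 0.497 for the others, with 11 to 16 markers past the threshold. More stromal cells, more matrix transcription in each, or a lower share of endocrine cells stay open as hypotheses (1 of the 22 symbols stands in another list, and with 1 surrogate variable in place of the block Sparc was at −0.024).

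Other splits of the libraries tested chance. At 6 weeks a real count of 0 genes is matched by any split (100 of 100, highest other 386), which tests nothing. The 16 lists there were matched by 24 of 100 (highest other 23, median of the others 13), so chance cannot be excluded for them. At 18 weeks 3 of 100 splits gave as many as 75 genes and 2 of 100 as many as 26 lists, shares under 5%. These 100 were taken from 462 possible splits, so the shares are rough. They make chance less likely and do not exclude it. Still, the highest others were 621 genes and 28 lists, and the median of the others was 11 lists. The split with 621 set vehicle 1, 2, 3 and 6 with cadmium 5 against the rest, and a split with several times the real count points to another structure among these libraries. In culture without pairs 6 of 100 splits gave as many as 1 gene (highest other 176) and 37 of 100 as many as 12 lists (highest other 19, median of the others 9), so chance cannot be excluded for these counts. With the block the real split stood highest, 223 genes against 11 and 16 lists against 13 over 16 splits (1 of 16 for each). But 16 splits are too few for a share under 0.05. The vehicle comparison had 14756 genes in 1 of 100 splits (highest other 11774, a split that differs from the real one by 18 week vehicle library 6 alone). Its 21 lists were matched by 18 of 100 (highest other 27). The differences between settings gave 382 genes in 2 of 100 splits (highest other 691), 4 genes in 12 of 100 (highest other 465) and 0 genes, which any split matches (100 of 100, highest other 12).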

How the results depend on the processing

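The blocked variations in culture and the fits without the 3 libraries of lowest depth were tests chosen after the result was seen. Most values for single genes and lists kept their direction and side of the threshold (2857, against 461 weaker, 257 stronger and 104 of opposite sign). Values that passed in neither fit count as kept, so this tally does not measure how firm the calls were. Among counts, shares and overlaps 205 stayed, 92 moved, 5 were weaker and 6 of opposite sign. Depth was lowest in 3 libraries of 18 weeks, at 9092759 to 21573301 counts, which limits what they show of low genes. Where no cause is given, the cause was not tested. Calls at 6 weeks were 11 by DESeq2 and 1 in the fit of all 30 libraries (0 to 1 with a library left out). At 18 weeks they were 765 by DESeq2 (74 of the 75 among them), 140 without a count filter, 2496 in the fit of all 30 libraries, and 257 at a threshold of 0.1. They were 0 with the acinar share as a covariate, with acinar and Reg genes left out, with library weights, with a surrogate variable or without the 3 shallow libraries, where fewer samples were fitted (0 to 318 with a library left out). In culture they were 7 without a filter, 0 in the fit of all 30 libraries, and 1 to 2 with a library left out. With the replicate block they were 223, or 117 with DESeq2, 256 with library weights and 222 with RLE (100 to 269 with a pair left out). Of these 223 only Mt1 was also called without pairs. The numbers of the in vivo libraries were not taken to pair them, since not every same-number correlation was over 0.1, although 3 of 5 were at 18 weeks. Same-number correlations ran from −0.173 to 0.309 at 6 weeks, with 1 of 4 cadmium libraries closest to its own number. They ran from −0.0106 to 0.401 at 18 weeks, with 2 of 5. A replicate block gave 0 calls at 6 weeks and 1 at 18 weeks, over the numbers both groups share, and 16 and 28 lists. The vehicle comparison had 9642 calls with the acinar covariate. Differences between 18 and 6 weeks numbered 1385 by DESeq2, 192 without a filter, 0 on the 4 in vivo groups and 2546 without the 3 shallow libraries (0 to 1694 with a library left out). Those between culture and 18 weeks numbered 196 by DESeq2, 1057 without the shallow libraries and 0 with the culture pairs as a replicate block (0 to 358 with a library left out). Those between culture and 6 weeks numbered 3 by DESeq2 (0 to 1). Lists called numbered 0 with an estimated correlation in each setting, 0, 11 and 0 by fry at 6 weeks, 18 weeks and in culture, and 15 at 18 weeks with the acinar covariate. Shared calls were 5 for 6 and 18 weeks by DESeq2 and 2 for 18 weeks and culture with the block. With a library left out, the acinar difference at 18 weeks was 4.41 to 8.86 points, the insulin difference −0.424 to 1.19, that of the 10 top genes −1.99 to 0.154, and the erythroid difference in culture −3.32e-06 to 1.01e-05.

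Signs turned for some genes, among them Slc39a5 and Tff2, which had risen at 18 weeks, and Sparc, which rose in culture with the block. With the acinar covariate at 6 weeks Nqo1 was at −0.20, Ins1 at 0.0013, Pdx1 at −0.072, Mafa at −0.0020 and Slc39a8 at −0.022. Without a filter Nqo1 was at −0.00073. With library weights Nqo1 was at −0.051 and Pdx1 at −0.038. With a surrogate variable Hmox1 was at 0.036, Pdx1 at −0.067 and Slc2a2 at −0.10. At 18 weeks the covariate gave Hmox1 −0.059, Nqo1 −0.29, Gcg 0.038, Pdx1 0.012, Mafa −0.062, Slc2a2 0.11, Slc30a8 0.028, Slc39a5 −0.23, Prdx4 −0.33, Reg1 −0.67 and Tff2 −0.19. Gcg was at 0.043 without the shallow libraries. Mafa was at −0.0025 by DESeq2, −0.0046 with RLE, −0.0034 without a filter, −0.0028 without acinar and Reg genes, −0.016 with library weights and −0.0033 with all 30 libraries. In culture Hmox1 was at 0.076 and Mafa at 0.011 with the covariate, and Mafa at 2.8e-05 with RLE. With a surrogate variable Nqo1 was at −0.17, Ins2 at 0.0022, Pdx1 at 0.0099, Mafa at 0.043 and Sparc at −0.024. The difference for Slc30a1 between 18 and 6 weeks was −0.027 without the shallow libraries. Lists that turned with the covariate were cell cycle at 6 weeks (adjusted p = 0.696) and, at 18 weeks, the integrated stress response (0.177), Reg family (0.0114), acinar (0.0375), stellate (0.991) and Schwann markers (0.0263). With single libraries left out, ranges that crossed 0 at 6 weeks were Hmox1 −0.18 to 0.00048, Nqo1 −0.068 to 0.075, Pdx1 −0.075 to 0.095 and Slc2a2 −0.032 to 0.16. At 18 weeks they were Nqo1 −0.038 to 0.16, Sst −0.070 to 0.14, Mafa −0.058 to 0.075 and Slc2a2 −0.087 to 0.056. In culture they were Hmox1 −0.17 to 0.092, Nqo1 −0.057 to 0.15, Gcg −0.0055 to 0.039, Pdx1 −0.088 to 0.0034 and Mafa −0.17 to 0.10. For differences between settings they were Slc30a1 −0.082 to 0.11 (18 against 6 weeks), −0.018 to 0.080 (culture against 18 weeks) and −0.060 to 0.13 (culture against 6 weeks), and Mt1 −0.34 to 0.011 (culture against 18 weeks).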

Other observations

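The comparison of list directions between times was a test chosen after the result was seen. Medians of immune cell genes had opposite signs at the 2 times in vivo, and each side rested on part of the libraries. The 22 macrophage and MHC class II markers had a median log2 fold change of −0.38 at 6 weeks (0 of 22 higher) and 0.40 at 18 weeks (21 of 22 higher), and lymphocyte markers −0.44 and 2.56. Medians were similarly placed for interferon response genes (−0.17 and 0.30) and class I antigen presentation genes (−0.14 and 0.38). The change of sign was not particular to immune genes. Stellate, endothelial, ribosomal protein, proteasome and fatty acid oxidation lists had it too. At 6 weeks macrophage markers stood at 0.15 to 0.43 in vehicle libraries 1 to 3 and at −0.63 and −0.29 in vehicle 4 and 5 (mean log2 CPM minus the vehicle mean), and cadmium libraries were at −0.998 to −0.198. At 18 weeks lymphocyte markers stood at 1.45 to 3.69 in cadmium libraries 2 to 4 and at −1.07 and −0.59 in cadmium 1 and 5. The interaction test passed for Cd163 (1.20 at 18 weeks, −2.42 at 6 weeks, difference 3.60 ± 0.80, edgeR adjusted p = 0.0329), but not in the fit of the 4 in vivo groups (adjusted p = 0.155), and differences of whole lists between times were not tested.

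Every library of 18 weeks, vehicle or cadmium, had Rn7sk far above its level in the others. Rn7sk held 3.18% ± 0.947 of counts in vehicle (SD, n = 6) and 3.65% ± 1.01 in cadmium libraries (SD, n = 5), against 0.00014 to 0.00030% on average in the groups of 6 weeks and culture. CT010467.1 held 4.82% ± 4.81 and 2.78% ± 2.27 at 18 weeks and 0.126 to 0.141% on average elsewhere, but 18 week vehicle library 1, at 0.1475%, lay within the range of the libraries of 6 weeks and culture.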
